A study of Mus musculus with 2 samples.

How the data were processed

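RNA from mouse primary enteroids was sequenced after incubation with the gut bacterium Bifidobacterium longum (B. longum) and without it. Enteroids are structures of intestinal epithelium grown in culture from isolated crypts or stem cells. The labels give 1 sample for each of the 2 groups and an age of 8 weeks. They mention 3 biological replicates, but the deposited table holds 1 column per group, and how the replicates were combined is not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into Illumina libraries. Whether polyadenylated RNA was selected, whether the libraries kept strand, and how long the incubation lasted are not given in the sources used here.

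The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 value per gene and group. The submitters' processing notes name fastp, HISAT and RSEM with the genome build GRCm38.p5, without versions. The table has 52269 rows, of which 51633 matched a mouse gene symbol by Ensembl identifier and 636 did not. Among the latter, 357 have identifiers of the kind given to assembled transcripts. Gene types, coordinates, transcript lengths and GC content were taken from GENCODE M21 on GRCm38, by gene identifier.

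The deposited FPKM values have the form of numbers with 2 decimals multiplied by 1 factor per column. The factor found was 0.998 for B. longum, where 100% of values between 0.5 and 20 FPKM equalled such a product to 3 decimals. It was 1.002 for control, where 99.9% did. With the last decimal drawn at random, the best factor fitted 11.2% and 11.1% of values. The authors' scaling between columns is inferred from the values and is not described in the sources used here. Removing the factors was 1 of the alternatives.

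Sequencing depth was estimated from the size of 1 fragment's FPKM step in genes with a single transcript of 400 to 4000 nt. For B. longum, 28600000 fragments with a mean length of 300 nt put 88.7% of 1009 genes within 0.15 of a whole number of fragments, against 34.1% with shuffled lengths. For control, 25600000 fragments with a mean length of 295 nt put 87.9% of 1184 genes within 0.15, against 34.6% with shuffled lengths. Fragments per gene were then estimated from FPKM, the depth and the median transcript length less 297.5 nt, where at least 50 nt were left. These estimates add up to 64.9% of the B. longum and 64.5% of the control fragments, so they are approximate. From them an exact Clopper-Pearson 95% interval was computed for each FPKM ratio. The intervals cover counting error only and not the spread between cultures. No ratio is given against a value listed at 0.

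The planned test was limma on log2(FPKM + 1) with camera for the gene lists. With 1 column per group neither can be run, and no p-value is given. Differences are of log2(FPKM + 1), B. longum minus control, for the 12202 genes with a mean of at least 1 FPKM, and a size of at least 1 was used to count genes. The pseudocount makes this scale understate differences of low genes. The 32 gene lists were fixed before the data were examined. For lists with at least 5 measured members, the median difference was ranked among the medians of 10000 random lists of protein-coding genes with the same size, matched on mean expression in 20 bins. This percentile describes these libraries. Genes of a pathway vary together more than random genes do, so a list can leave the central 95% without an effect of the treatment.

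Named genes followed a rule fixed before the data were examined, except for 1 part. The first part took the 8 largest differences in each direction among genes with at least 5 FPKM in the higher library, without unnamed and predicted genes. The second part asked for the members of each list with the smallest adjusted p, which do not exist here. Once the table was seen to have 1 column per group, it was replaced by up to 2 members per list with the largest absolute difference and at least 5 FPKM in the higher library. The third part always took Lgr5, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi, Mki67, Reg3b, Reg3g, Tlr2 and Cdh1. Other list members are named as examples, chosen after their values were seen. The 6 added gene lists were written from general knowledge after the fixed lists and some of their own members had been looked at, but before their medians were computed.

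The procedure was tested on simulated libraries with counting noise alone, built from 41909 genes at the depths above. The depths put in were recovered. Of 100 genes made to differ 3-fold, 99% passed the size of 1, as did 36% of those made to differ 2-fold. Among 11572 unchanged genes, 12 passed it. Only genes with a fragment estimate were simulated, so genes with a median transcript under 300 nt were left out. Among 191 real genes with a difference of at least 1, at least 5 FPKM and an annotated length, 40 were that short. The count of 12 thus does not cover short transcripts and is no error rate for the real differences. Of 100 unchanged lists of 25 genes, 3 left the central 95%, and with a shift of 0.2 all 100 lay above it. The simulated genes varied independently and by counting noise alone, so these list rates do not carry over to the real lists. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling to equal totals, median-of-ratios scaling and quantile normalization. Further alternatives, listed in the closing section, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.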

Results

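Gene expression was measured by RNA sequencing in 1 library of control mouse enteroids and 1 library of enteroids incubated with B. longum. Library stands here for the 1 column of values per group, and how the labels' 3 replicates were combined in it is not given. The comparison asks which transcripts of the intestinal epithelium differ in the presence of this commensal. The estimated depth was 25600000 fragments for control and 28600000 fragments for B. longum. At least 1 FPKM was reached by 12233 genes in control and 12066 in B. longum. The 10 highest genes took 20.9% of all FPKM in control and 20.8% in B. longum. Across the 12202 genes compared, the Pearson correlation of log2(FPKM + 1) between the libraries was 0.97, over genes that are not independent replicates. With 1 library per group, no difference below has a replicate check, and intervals in parentheses are 95% counting intervals only.

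In the B. longum library, goblet cell, Paneth cell, antimicrobial, proliferation and mitochondrially encoded transcripts were lower as lists. Hypoxia, glycolysis and cholesterol synthesis transcripts were higher. The list medians of the log2(FPKM + 1) difference were 0.28 for hypoxia and glycolysis and 0.20 for cholesterol and fatty acid synthesis. Muc2, the main secreted intestinal mucin, was at 110 FPKM against 153 in control, 1.40-fold lower (1.31 to 1.501). Reg3g, an antibacterial lectin, was 2.46-fold lower (2.19 to 2.78), and the transcription factor gene Myc was 4.80-fold lower (4.02 to 5.75). Adm, which encodes the hypoxia-inducible peptide adrenomedullin, was 3.37-fold higher (2.96 to 3.86). It was the only 1 of 32 hypoxia and glycolysis list members with a difference of at least 1. Most genes were close between the libraries, and 10387 of 12202 (85.1%) differed by less than 0.5 on the log2(FPKM + 1) scale.

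A difference of at least 1 on this scale was found for 338 genes, 132 higher and 206 lower with B. longum. At 1.5-fold, a threshold added after seeing the data, there were 502 higher and 787 lower. With protein-coding genes alone, 62 were higher and 100 lower, and with quantile normalization 155 were higher and 166 lower. The median difference over all genes compared was -0.03, with an SD across genes of 0.46. Of the 338 genes, 82 were listed at 0 in 1 of the libraries, and only 6 of those were protein-coding.

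**Figure D1:**
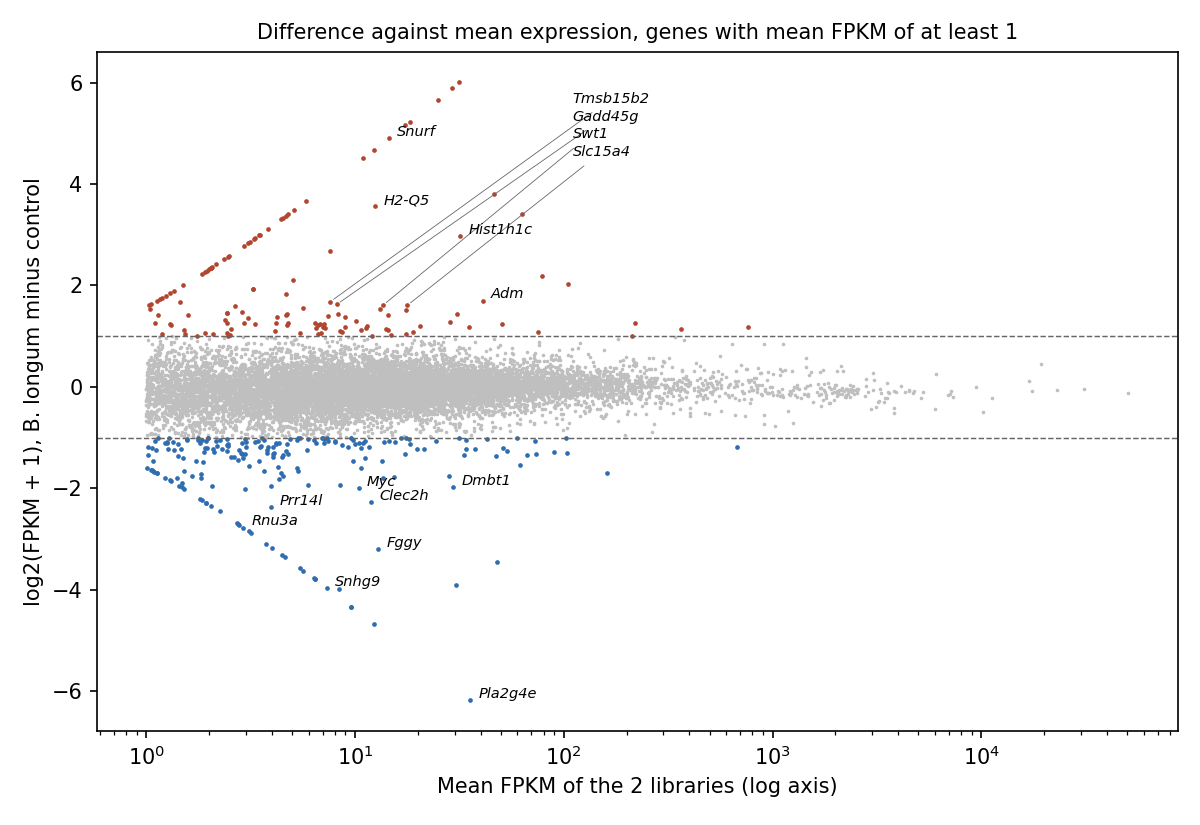
Difference in log2(FPKM + 1), B. longum minus control, against the mean FPKM of the 2 libraries on a log axis, 1 point per gene. Coloured points lie at or beyond 1 in either direction (132 red, higher; 206 blue, lower), and the named genes are the 8 largest in each direction after unnamed and predicted genes were left out; the straight outer bands are genes listed at 0 in 1 library.

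Among named genes at or above 5 FPKM, the largest difference toward lower values was that of Pla2g4e (ENSMUSG00000050211), a phospholipase A2 gene on chromosome 2 from 120166412 to 120245335 (GRCm38, minus strand). It was at 71.1 FPKM in control and was listed at 0 with B. longum. Fggy, a carbohydrate kinase gene, was at 24.2 FPKM in control and 1.73 with B. longum, 14.0-fold lower (8.78 to 23.1). Prr14l was 11.9-fold lower (7.98 to 18.9), and the lectin-like receptor gene Clec2h was 5.96-fold lower (4.47 to 7.93). Myc (ENSMUSG00000022346, chromosome 15 from 61985391 to 61990374, plus strand) was at 17.2 FPKM in control and 3.59 with B. longum. Dmbt1, which encodes a secreted mucosal scavenger receptor, was at 47.7 and 11.3 FPKM, 4.21-fold lower (3.92 to 4.52). The short non-coding genes Snhg9 and Rnu3a were at 14.6 and 5.84 FPKM in control and were listed at 0 with B. longum. Snhg9 lies antisense to another gene and Rnu3a has a near-identical copy, so both are uncertain.

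Toward higher values, Hist1h1c (ENSMUSG00000036181), a linker histone gene on chromosome 13 from 23738808 to 23740367, was at 57.4 FPKM with B. longum and 6.43 in control, 8.92-fold higher (7.74 to 10.4). It belongs to the histone list, which is given below among the measures of RNA composition. Adm (ENSMUSG00000030790, chromosome 7 from 110627661 to 110629820, plus strand) was at 63.2 and 18.7 FPKM. The stress-inducible gene Gadd45g was 3.68-fold higher (2.76 to 4.95), Swt1 3.38-fold (2.78 to 4.15) and the peptide transporter gene Slc15a4 3.29-fold (2.56 to 4.26). H2-Q5, annotated as a polymorphic pseudogene of the major histocompatibility complex, was at 23.8 against 1.10 FPKM. Snurf was at 28.9 FPKM with B. longum and listed at 0 in control, while Snrpn, which overlaps it on the same strand, was at 13.3 and 8.50 FPKM. Tmsb15b2 was at 12.1 and 3.10 FPKM. H2-Q5, Snurf and Tmsb15b2 share sequence with paralogs or overlapping genes and are uncertain.

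The goblet cell list had a median difference of -0.48, below all 10000 matched random lists, and 20 of its 21 measured members were lower with B. longum. Tff3, a trefoil peptide of mucus, was at 2058 FPKM in control and 1655 with B. longum, 1.24-fold lower (1.21 to 1.28). Agr2, needed for mucin folding, was 1.60-fold lower (1.51 to 1.69). Atoh1, the transcription factor gene of the secretory lineage, was at 3.19 and 1.12 FPKM, 2.85-fold lower (2.10 to 3.95). Spdef, which acts in goblet cell maturation, was 1.73-fold lower (1.43 to 2.11). Tpsg1 and Gcnt3 were at 16.01 and 12.02 FPKM in control and at 8.05 and 6.30 with B. longum.

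The antimicrobial and mucosal defence list, which shares members with the goblet and Paneth cell lists, had a median of -0.49, also below all random lists, with 11 of 13 members lower. Without the filter on mean FPKM its median was -0.14, and that of the Paneth list -0.20, both still below the central 95%. Reg1 was at 6.85 FPKM in control and 1.04 with B. longum, and Reg3b at 16.7 and 5.71, which is 2.93-fold lower (2.02 to 4.27). Itln1, an abundant intestinal lectin, was at 1296 and 764 FPKM, 1.70-fold lower (1.66 to 1.74). The Paneth cell list had a median of -0.31, with 14 of 20 members lower, below all random lists. Defa30 was at 13.3 and 8.04 FPKM, a difference within its counting interval. Lyz1, the lysozyme gene of Paneth cells, was 1.11-fold lower (1.06 to 1.16). The enteroendocrine list lay inside the central 95% of random lists, with a median of -0.11 and 17 of 26 members lower. Chga, a granule protein of enteroendocrine cells, was at 33.5 FPKM in control and 32.7 with B. longum. Cck was at 56.5 and 40.3 FPKM, Sst at 27.2 and 39.5, and Neurog3, the enteroendocrine progenitor factor gene, at 4.33 and 1.26. The tuft cell list had 6 measured members and a median of 0.12, at percentile 88.8, and of 0.02 without the filter on mean FPKM. Among these members was Ptpn6, with a difference of 0.06. The tuft cell marker Dclk1, at 1.496 FPKM with B. longum and 0.371 in control, did not reach the mean of 1 FPKM. It is not among these members.

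The hypoxia and glycolysis list had a median of 0.28, above all 10000 random lists, with 29 of 32 members higher with B. longum. Ero1l, an oxidase of protein folding in the endoplasmic reticulum, was at 496 FPKM with B. longum and 261 in control, 1.90-fold higher (1.79 to 2.02). Hexokinase 2 (Hk2) was 1.74-fold higher (1.59 to 1.91). Ldha and Vegfa were 1.25-fold higher each, with intervals of 1.22 to 1.27 and 1.17 to 1.34. The cholesterol and fatty acid synthesis list had a median of 0.20, again above all random lists, with 26 of 32 members higher. Fdft1 and Sqle, which act in sequence in squalene metabolism, were at 90.3 and 127 FPKM with B. longum and at 56.1 and 81.7 in control, 1.61-fold (1.53 to 1.70) and 1.55-fold higher.

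The intestinal stem cell list had a median of 0.21, at percentile 99.9, with 16 of 21 members higher. With a mean of at least 5 FPKM required, the median was 0.14 at percentile 96.3, inside the central 95%. Rnf43, a Wnt feedback inhibitor, was at 13.3 FPKM with B. longum and 4.53 in control, 2.94-fold higher (2.56 to 3.38). Lgr5, the marker of crypt base stem cells, was at 46.2 and 34.7 FPKM, 1.33-fold higher (1.26 to 1.41), whereas Olfm4 was at 18.4 and 24.2 FPKM, 1.32-fold lower (1.19 to 1.46). Clca3b was at 28.4 and 50.7 FPKM. The Wnt signalling list, which also contains Rnf43 and Myc, had a median of 0.10, at percentile 96.2, and the Notch and Bmp list one of -0.17, at percentile 7.24. Without the filter on mean FPKM these were 0.03 and -0.09. In the latter, Id1 was at 20.1 FPKM in control and 9.88 with B. longum, and Id2 at 16.3 and 29.8. The proliferation and cell cycle list had a median of -0.25, below all random lists, with 31 of 35 members lower. Mki67 was 1.28-fold lower (1.23 to 1.33), Ube2c 1.55-fold (1.47 to 1.63) and Cdc20 1.503-fold (1.32 to 1.71), while Pcna was at 231 and 233 FPKM.

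**Figure D2:**
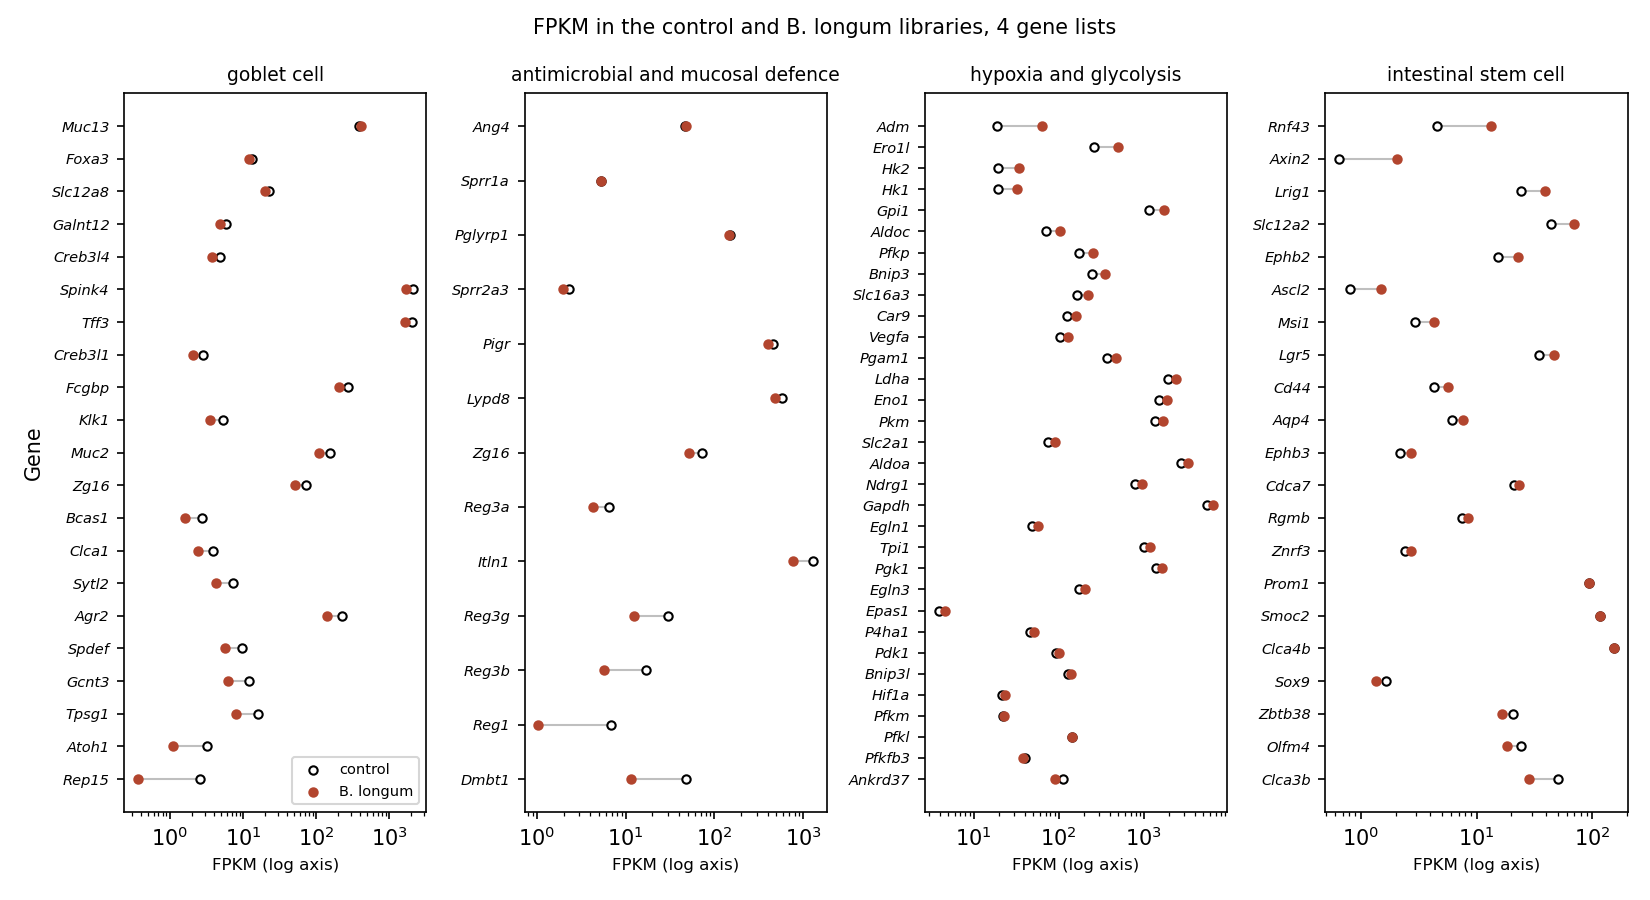
FPKM on a log axis in the control (open circles) and B. longum (filled circles) libraries for the measured members of 4 gene lists, sorted by difference. In the goblet cell list 20 of 21 filled circles lie to the left of the open ones, and in the hypoxia and glycolysis list 29 of 32 lie to the right.

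Single immune genes differed in both directions, while none of the lists named next stayed outside the central 95% in every setting. The Toll-like receptor and NF-kB list had a median of -0.15, at percentile 4.58, and of -0.03 without the filter on mean FPKM. Tlr3 was 2.64-fold lower (1.74 to 4.27) and Sigirr, a negative regulator of such receptors, 2.10-fold lower (1.82 to 2.42). Tlr2 was at 0.0400 and 0.0600 FPKM, too low to compare. Of 9 measured cytokines and chemokines (median 0.04, percentile 74.2, but 0.35 at percentile 99.6 with a mean of at least 5 FPKM), Ccl20 was 4.77-fold lower (2.74 to 9.18) and Cxcl16 2.38-fold higher (1.99 to 2.84). The interferon-stimulated list had a median of 0.16, at percentile 99.3, with 10 of 19 members higher and 9 lower. Without the filter on mean FPKM its median turned to -0.04 at percentile 35.7, and with quantile normalization it was at percentile 96.8, inside the central 95%. Its Oasl1 was at 26.1 FPKM with B. longum and 15.9 in control, and Irf7 at 6.52 and 3.91. The antigen presentation list had a median of 0.08, at percentile 89.5, with H2-Q7 at 7.91 and 4.84 FPKM and Psmb10 at 24.5 and 34.3.

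The immediate early and heat shock list had a median of -0.11, at percentile 9.74, with 12 members higher and 15 lower, of which 3 each way by at least 1.5-fold. Hspa1a was 3.50-fold higher (2.90 to 4.23) and Atf3 2.74-fold higher (2.36 to 3.21), while Hspa8 was 1.63-fold lower (1.60 to 1.67). The apoptosis and p53 list had a median of 0.01, at percentile 63.4, with Gadd45b 2.40-fold higher (2.12 to 2.74) and Cdkn1a 1.92-fold higher (1.84 to 2.01). In the unfolded protein response list (median 0.00, percentile 54.1), Asns and Trib3 were 1.56-fold (1.39 to 1.74) and 1.59-fold (1.23 to 2.05) higher. The oxidative stress list had a median of 0.01, at percentile 64.2, with Hmox1 at 19.9 FPKM with B. longum and 14.2 in control and Gpx2 at 471 and 658. The aryl hydrocarbon receptor list had a median of -0.08, at percentile 4.02 and at 2.36 without the filter on mean FPKM, although its target genes Tiparp and Cyp1a1 were 2.36-fold (1.90 to 2.96) and 1.86-fold (1.72 to 2.01) higher.

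The enterocyte absorption and digestion list had a median of -0.08, at percentile 6.20, which was 0.00 with quantile normalization. Its members with the largest differences were Slc51b, a bile acid transporter subunit gene, at 6.72 FPKM with B. longum and 3.30 in control, and Apoc3 at 88.0 and 56.5. Alpi, an alkaline phosphatase of the brush border, was at 13.6 and 15.0 FPKM, within its counting interval. The fatty acid oxidation list (median 0.00, percentile 52), the oxidative phosphorylation list (0.03, percentile 82.9) and the junction list (0.07, percentile 88.5) lay inside the central 95%. Their members included Acsl5 at 254 FPKM with B. longum and 189 in control, Acot2 at 6.06 and 8.15, Cox5b at 211 and 244, and Ndufa1 at 186 and 233. In the junction list, Cldn23 and Gjb1 were at 13.1 and 47.6 FPKM in control and 6.09 and 24.1 with B. longum, and Cdh1, the E-cadherin gene, was 1.16-fold higher (1.13 to 1.19). The regenerative and fetal-like list had a median of 0.05, at percentile 80.3, with Areg, an EGF family ligand, 2.53-fold higher (2.25 to 2.85) and Anxa3 1.81-fold higher (1.43 to 2.29).

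Markers of other cell types were nearly undetected. Of the fibroblast and smooth muscle list 2 members passed the filter, with Myl9 at 20.2 FPKM with B. longum and 8.66 in control and Vim at 3.67 and 5.89. The leukocyte list had 1 such member, with a difference of 0.38, and the endothelial and neural list 2, with a median of -0.14. The list of colon and stomach epithelium had a median of -0.08, at percentile 26.4, with Slc26a3 at 38.5 and 71.5 FPKM and Cdx1 at 46.1 and 76.9.

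Measures of RNA composition also differed between the libraries, beside all of the groups above. The mitochondrially encoded list had a median of -0.38 (-0.21 under quantile normalization), below all random lists, with 11 of 11 members lower with B. longum. The largest differences were those of mt-Nd1, at 3145 against 4498 FPKM, and mt-Co2, at 185 against 346. The share of all FPKM taken by mitochondrially encoded protein genes differed less, at 10.8% with B. longum and 11.7% in control. The mitochondrial ribosomal RNAs went the other way, with mt-Rnr1 at 819 against 454 FPKM and mt-Rnr2 at 1059 against 464. The ribosomal protein list had a median of -0.08, at percentile 1.53, but -0.01 under quantile normalization, and 41 of 45 members were lower, among them Rpl13 at 593 against 880 FPKM and Rpl10a at 1803 against 2156. The histone list had a median of 0.14, at percentile 95.5, with 5 members higher and 5 lower, and turned to -0.15 with a mean of at least 5 FPKM. It lay above the central 95% at 0.27 and 0.21 with pseudocounts of 0.1 and 0.5, and at 0.24 without a filter. Hist1h4i was at 10.4 FPKM with B. longum and 3.80 in control.

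Of 29 lists with at least 5 measured members, 4 lay above and 6 below the central 95% of random lists, where 1.45 would do so by chance if genes varied independently. All values compare these 2 libraries, so differences between cultures of the same group, which were not measured here, are part of them.

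**Figure D3:**
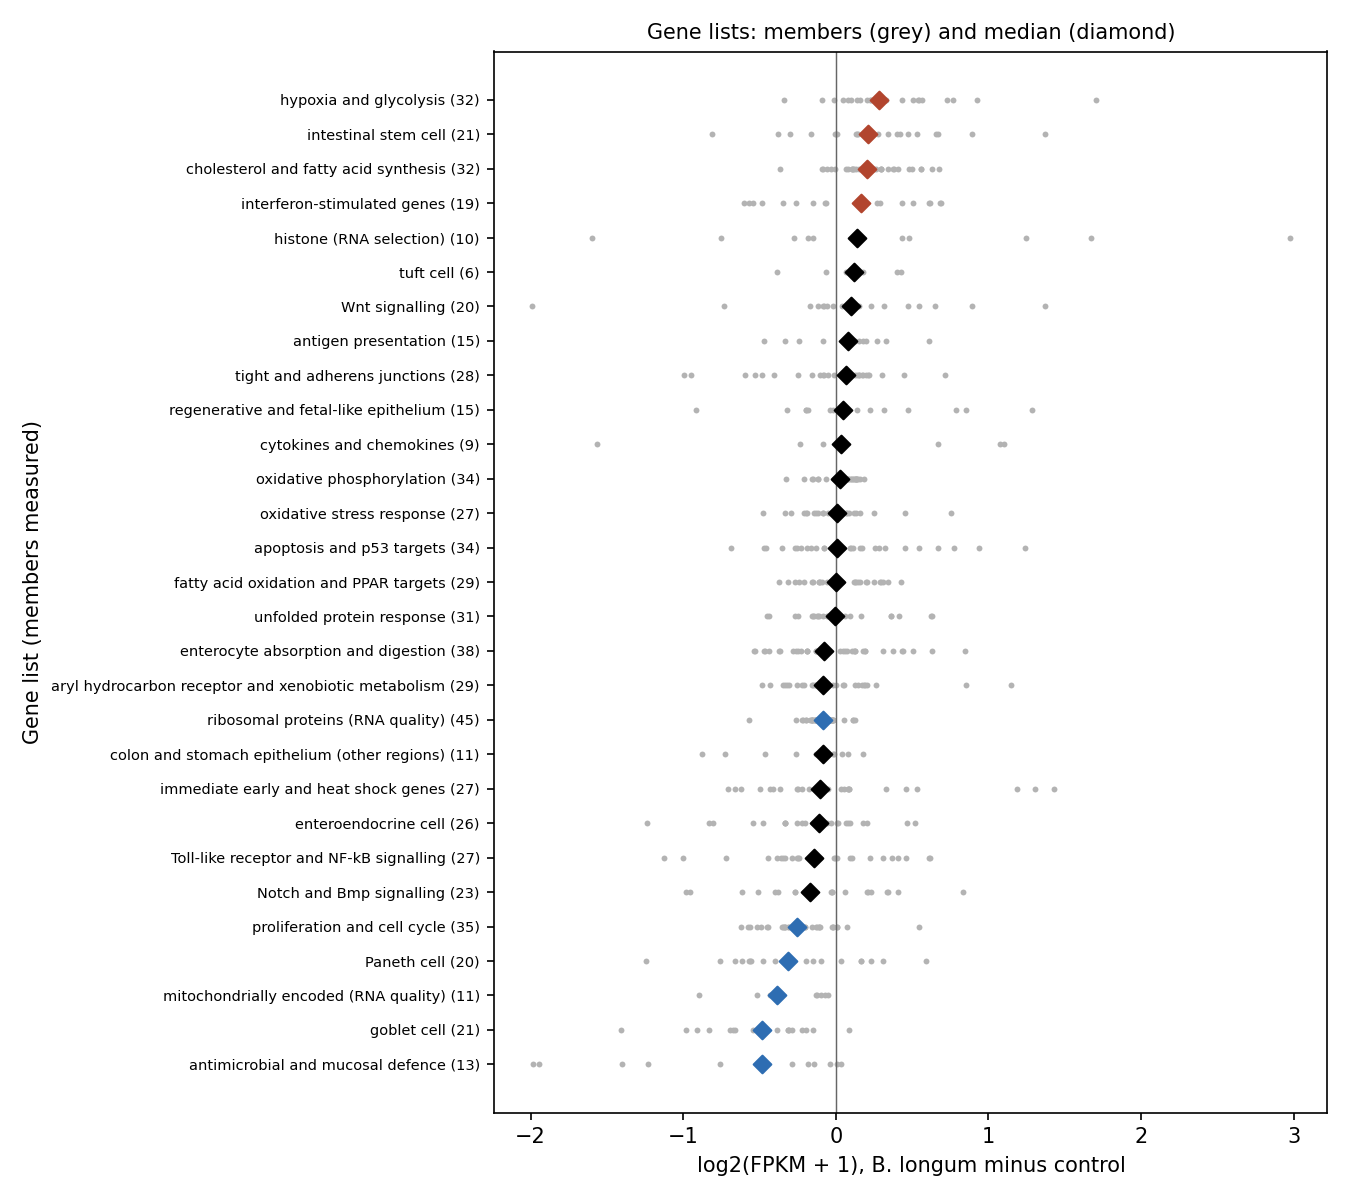
Difference in log2(FPKM + 1), B. longum minus control, of each measured member (grey points) and the median (diamonds) of 29 gene lists, with the number of members in parentheses. Red diamonds (4) lie above and blue diamonds (6) below the central 95% of 10000 matched random lists, from 0.28 for hypoxia and glycolysis down to -0.49 for antimicrobial and mucosal defence.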

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

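The settings that removed the column factors, kept protein-coding genes alone, left out transcripts under 300 nt, removed a GC and length trend or used 1.5-fold were chosen after seeing the data. The 338 genes with a difference of at least 1 (132 higher, 206 lower) became 636 (234 and 402) with a pseudocount of 0.1 and 146 (63 and 83) with a mean of at least 5 FPKM, where fewer genes were tested. They became 162 (62 and 100) among protein-coding genes and 1289 (502 and 787) at 1.5-fold. The other 8 settings stayed within 1.5 times of 338, from 271 to 449. The lean toward lower values depended on scaling, with 155 higher and 166 lower under quantile normalization and 149 and 192 after rescaling to equal totals. The goblet, antimicrobial, Paneth, proliferation, hypoxia, cholesterol and mitochondrially encoded lists stayed on their side of the central 95% in all 11 alternatives that apply to lists, though the antimicrobial median moved to -0.14 and the Paneth median to -0.20 without a filter, and the mitochondrial one to -0.21 with quantile normalization. The interferon-stimulated median became -0.035 without a filter and 0.16, inside the range, with quantile normalization. The stem cell median fell inside it at 0.14 with a mean of at least 5 FPKM. The ribosomal protein median lay inside at -0.083 with that filter and at -0.0060 with quantile normalization. Fixed lists that newly left the range were histones (0.27 and 0.21 with pseudocounts of 0.1 and 0.5, 0.24 without a filter), aryl hydrocarbon receptor (-0.074 without a filter) and cytokines (0.35 at 5 FPKM). Of the 19 fixed lists inside the range, 5 turned sign in an alternative, namely histones (-0.15 at 5 FPKM), absorption, oxidative stress, regenerative and unfolded protein response. The cause was not tested for these lists. Of 829 recomputed values of named genes with a counting interval, 13 moved by more than the distance from its middle to its bound on the log2 scale, and no gene with a difference of at least 1 turned direction. Settings that only change which genes are kept leave each gene's value as it was, and a change of pseudocount cannot turn a direction. These counts are therefore weak evidence that single genes are stable. No paired analysis was possible because the table has 1 column per group. For the same reason the limma variants, the replicate block and leaving out replicates were not run. Depth limits low genes, since 1140 of 11761 had under 50 estimated fragments in control.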

Other observations

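All tests below were chosen or fixed in outcome only after results were seen. The added lists were written from general knowledge before their medians were computed, but after some of their members and the fixed lists had been looked at.

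In a list of 18 iron regulation genes, 4 were at least 1.5-fold higher with B. longum, and the list as a whole did not stand apart, with a median of 0.05 at percentile 82.7 of matched random lists. These 4 were picked for their values. Tfrc, the transferrin receptor gene, was at 102 FPKM with B. longum and 47.7 in control, 2.14-fold higher (counting interval 1.95 to 2.36). Slc11a2, the divalent metal transporter gene, was 2.01-fold higher (1.89 to 2.14), Cybrd1, a brush border ferric reductase gene, 1.73-fold (1.67 to 1.78) and Slc39a14 1.66-fold (1.52 to 1.81). The ferritin genes Fth1 and Ftl1 were at 1460 and 3606 FPKM with B. longum and 1449 and 3440 in control.

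Of 5 measured EGF family ligands, Areg was the member that differed most, while Hbegf was at 3.53 and 3.58 FPKM and Tgfa at 6.39 and 6.16. The list's median was 0.24, at percentile 95.8, but 0.41 at percentile 98.5 with a pseudocount of 0.1 and 0.04 at percentile 78.7 without a filter. The 17 measured replication-dependent histones had a median of 0.40, above all random lists, with 10 higher and 7 lower. It was 0.66 with a pseudocount of 0.1, 0.90 with a mean of at least 5 FPKM and 0.26 without a filter. Of the 58 genes listed, 18 are also in the fixed histone list, so this is not a separate result. That fixed list had a median of 0.14, inside the central 95%, with 5 members higher and 5 lower. Replication-dependent histone transcripts mostly lack a poly(A) tail. The 4 ribosomal RNA rows were all higher with B. longum, with a median of 1.00.

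A hypothesis is that the B. longum library holds an amino acid response driven by the transcription factor ATF4. None of the 33 genes listed for it were in a fixed list, 31 were measured and 30 were higher. Their median was 0.44 (bootstrap interval over genes 0.33 to 0.52), above all matched random lists. Cars and Yars, which encode aminoacyl-tRNA synthetases, were 1.89-fold (1.54 to 2.33) and 1.73-fold (1.49 to 2.00) higher, and the transporter gene Slc1a4 1.91-fold (1.74 to 2.11). Slc38a2, another amino acid transporter gene, was 1.69-fold lower (1.62 to 1.77). These values describe the genes that raised the hypothesis and are no test of it, and differences in culture medium, density or handling may equally lie behind them.

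The higher hypoxia and glycolysis genes were weighed against GC content, a wider hypoxia response and other differences between the cultures or libraries. Removing a GC and length trend left the median at 0.28. This correction had an SD of 0.03 across protein-coding genes, whose differences had an SD of 0.35. A GC and length trend of that kind was thus too small to account for this median. Other forms of such bias were not tested. Hypoxia targets outside the fixed list had a median of 0.31 (bootstrap interval 0.22 to 0.36) over 25 genes, 22 of them higher and 3 lower. Only 1 was at least 1.5-fold higher, and Bhlhe40 was 1.82-fold higher (1.74 to 1.91). The list was written after some of its members had been looked at, so its median is no independent test. A hypoxia response is a possible explanation only. A difference between the cultures or libraries other than the bacteria cannot be told apart from the treatment with 1 library per group, and mt-Rnr2 at 1059 against 464 FPKM shows that RNA composition differed too.

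The lower goblet cell genes were weighed in the same way. Removing the GC and length trend left the median at -0.49, with the same small correction. That trend was too small to account for this median too, and other forms of such bias were not tested. The enteroendocrine median lay 0.37 above the goblet median (bootstrap interval 0.11 to 0.58), but 9 of its 26 members were higher and 17 lower. Paneth genes, Atoh1, Neurog3 and Cck were lower, whereas Sst was at 39.5 against 27.2 FPKM and Chga at 32.7 against 33.5. The tuft cell median was 0.12, and Dclk1, which missed the filter on mean FPKM, was at 1.496 against 0.371. A lower share of every secretory cell type therefore stays open. A difference between the cultures or libraries other than the bacteria, such as their stage of differentiation, cannot be told apart from the treatment with 1 library per group.

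The largest single-gene differences may in part come from transcripts shorter than the sequenced fragments, whose FPKM rests on a very small effective length. Of 191 genes with a difference of at least 1, at least 5 FPKM and an annotated length, 20.9% (exact interval 15.4 to 27.4) had a median transcript under 300 nt, against 0.461% of 9118 other genes and 0 to 2.62% in random draws of 191 genes. Among 68 genes listed at 0 in 1 library with an annotated length, 50 were that short. Most of the 191 genes, Myc, Dmbt1 and Adm among them, have longer transcripts, so how much of the pattern short transcripts account for stays open. Pla2g4e, with a median transcript of 4306 nt and 0 against 71.1 FPKM, is not among the short ones. Only the median transcript of each gene was looked at, so this does not settle whether its value of 0 is real.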
